A study of Caenorhabditis elegans with 2 samples.

How the data were processed

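The study measured binding of EOR-1 by ChIP-seq in whole L3 larvae of the C. elegans strain OP81, which carries a GFP-tagged eor-1 transgene. The labels give 1 group and 2 biological replicates, and samples were grouped and numbered from those labels. The labels name eor-1 as the antibody target and describe the experiment as directed at the GFP-tagged protein, and they list a fragment size range of 150-350 with no unit. No extraction protocol was given.

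The authors deposited peak lists in the narrowPeak format on the genome builds ce10 and ce11. Per the deposited file lists, each replicate was called on its own against control data as input for the irreproducible discovery rate (IDR) procedure, which compares the ranks of peaks between replicates. A pooled list was called on the reads of both replicates, and the optimal list was made from the pooled list and both replicate lists by IDR thresholding. The ce10 lists named 1 control entry and the ce11 peak lists 2, so the builds differ in more than the genome. The control data were not analysed here. The aligner, the peak caller, their versions, the read filters and the IDR threshold are not given in the sources used here.

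The deposited signal value of each peak is the peak caller's own, with a normalization that is not given in the sources used here. It was used to rank peaks within a list and never compared between lists except by rank. The deposited −log10 q-value reached the same maximum in many peaks of each list (784 of the 6708 pooled ce11 peaks at 3.20), so it was not used for ranking. All peaks of a list had a common width (416 bp in replicate 1, 496 bp in replicate 2 and 404 bp in the pooled list on ce11), with 1 exception each in the list of replicate 2 and the pooled list. The exception in the pooled list was the tos-1 peak. Per the deposited file lists, the replicate and pooled lists hold background entries besides peaks, so their weaker entries are candidates and not called binding sites. Read depth is unknown. The precision of each share is set by the number of peaks, with exact (Clopper-Pearson) 95% intervals, and a count of 0 is given with the share that 3 counts would make.

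Annotation and sequence came from the WBcel235 assembly, which is ce11, with Ensembl release 115 genes, and the ce10 lists were used for counts, chromosome shares and replicate sharing only. All coordinates are 1-based on ce11. A peak was placed by its summit, in the order 5′ UTR, coding exon, 3′ UTR, noncoding exon, intron and intergenic. Only protein-coding genes were used for this placement, so intergenic means outside protein-coding genes and may include noncoding genes. A promoter peak had a protein-coding transcript start within 500 bp, and a gene was assigned to a peak when its start was the nearest and within 1000 bp. Summits of 2 lists were shared when within 200 bp. Candidates for comparison with the thresholded peaks were the pooled peaks more than 1000 bp from any of them. Matches to GAGACGCAGA with at most 1 mismatch, on either strand, and exact matches to GAGAGA were counted within 100 bp of the summit.

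Shares were compared by two-sided Fisher's exact tests. Chance sharing between replicates, and chance proximity to transcript starts, came from 1000 circular shifts of summits within chromosomes, with a one-sided permutation p. Fisher's exact tests of 23 gene lists were adjusted by the Benjamini-Hochberg method over the lists. These were the lists of Ras, MAPK and vulval genes, Wnt, Hox, SWI/SNF, Mediator, ribosomal proteins, histones, collagens, molting, chaperones, vacuolar ATPase, translation factors, epidermis and junctions, neurons and synapses, body wall muscle, intestine, germline, excretory system, heterochronic, insulin with stress and longevity, cell death, cell cycle and actin cytoskeleton. The 8-mers in the 500 strongest pooled peaks were compared with those in peaks ranked above 1000 in the same way, with adjustment over all 8-mers. Peaks are not biological replicates, so these p-values describe the deposited lists and not variation between cultures.

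The gene lists, the 10-base sequence, the rule for named genes and the tests of replicate sharing, promoter, sequence and X chromosome shares, gene lists, rank classes, noncoding RNA genes and the transgene region were fixed before the data were examined. All other tests were added afterwards, among them those of 8-mers, the density around summits, gene parts, peaks of ranks 34 to 500, promoter against other peaks, each chromosome and gene lists at the 1000 strongest peaks of single replicates. The rule took the genes assigned to the 15 strongest thresholded peaks, up to 3 members of each gene list assigned to a thresholded peak, and eor-1, eor-2 and unc-119, with peaks that had no gene named by position. Alternatives covered the distance that counts as shared, the number of strongest peaks, stricter and looser peak sets, each replicate on its own, the distance to transcript starts, the sequence window and sequence, the background and the genome build. Leaving out peaks near rRNA genes or on mitochondrial DNA removed 0 peaks. The methods were tested on simulated peaks. Of the sites planted in simulated peaks for the comparison of the 500 strongest with those above rank 1000, run on 6208 peaks, 100% were recovered, and the 3 highest ranked 8-mers were the planted ones. The planted copies were exact, inside the search window and in random sequence. Recovery therefore checks the code and not sensitivity in real sequence. A match occurred in 0.298% of simulated background peaks, against 8.34% of the real candidates above rank 1000. For sharing of the 1000 strongest peaks, 301 shared summits were found where 300 had been planted. For the lists at the 1000 strongest peaks, drawn on 2980 genes, 5.00% of null lists had a p below 0.05. These were drawn from the distribution that the test assumes, so they check the code only. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.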

Results

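Binding of the transcription factor EOR-1 was measured in L3 larvae of Caenorhabditis elegans by chromatin immunoprecipitation and sequencing. EOR-1 is a zinc finger protein with a BTB domain, related to human PLZF, and acts with EOR-2 in Ras and Wnt signalling. The animals were whole larvae, both sexes mixed, of strain OP81, which carries a transgene of GFP-tagged eor-1 in an unc-119 mutant background. There was 1 group with 2 biological replicates. For each replicate the authors' files give a peak list, and for both together a list called on pooled reads and a short list kept after thresholding on the irreproducible discovery rate (IDR), called the thresholded peaks here. On the ce11 genome replicate 1 had 2488 peaks and replicate 2 had 2610, the pooled list had 6708 candidates and the thresholded list had 33. Read depth is unknown, because the files used here give peaks and no read counts. The intervals given are exact (Clopper-Pearson) 95% binomial intervals and cover the counting of peaks only.

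The 33 thresholded peaks were led by sites upstream of tos-1, Y39E4B.6, ftt-2, his-37, iff-2 and hsp-1. The strongest peak, on chromosome V (9344236 to 9344422, ce11), had a signal value of 113.8 and its summit lay 95 bp upstream of the tos-1 start. Y39E4B.6 on chromosome III followed (13070473 to 13070876, signal 53.8, 81 bp upstream), and then a pair of neighbouring peaks upstream of ftt-2, a 14-3-3 protein gene on the X chromosome, with signal values of 51.8 (11605672 to 11606075) and 44.1 (11605900 to 11606303). The next gene peaks were at his-37, a histone H4 gene on chromosome V (9546826 to 9547229, signal 40.2, 77 bp upstream), at iff-2, which encodes the translation factor eIF5A, on chromosome II (8561287 to 8561690, signal 36.99, 122 bp upstream), and at hsp-1, a constitutive Hsp70 chaperone gene, on chromosome IV (17278379 to 17278782, signal 34.2, 378 bp upstream). The signal value is the authors' value for each peak and ranks peaks within a list only. The peaks at tos-1, Y39E4B.6, ftt-2, his-37, iff-2 and hsp-1 were all outside protein-coding genes (called intergenic here) in the Ensembl annotation.

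Among the 15 strongest thresholded peaks, 11 had a protein-coding transcript start within 1000 bp and 4 had none. Inside genes, a peak in an intron of let-526, which encodes an ARID subunit of the SWI/SNF chromatin remodelling complex, lay 874 bp downstream of the nearest start (chromosome I, 5312846 to 5313249, signal 32.6). A peak in an intron of zfp-1, the worm homologue of AF10, lay 710 bp upstream of the nearest annotated start (chromosome III, 8801907 to 8802310, signal 31.1). The gei-4 peak (chromosome III, 354922 to 355325, signal 30.4) and the ipla-6 peak (chromosome IV, 6336756 to 6337159, signal 30.2) lay 324 bp and 695 bp upstream. The 4 peaks with no start within 1000 bp were on chromosome I at 5637734 to 5638137 (signal 35.0), on chromosome II at 8787413 to 8787816 (signal 30.8), on chromosome III at 12612518 to 12612921 in an intron of Y111B2A.12 (signal 30.7), and on chromosome III at 13062430 to 13062833 (signal 30.5). Of all 33 thresholded peaks, 24 were intergenic, 8 were intronic, 1 lay in a 5′ UTR and 0 lay in a coding exon. The remaining members of the fixed gene lists with a thresholded peak were rpl-3, a ribosomal protein gene (chromosome III, 3867409 to 3867812, signal 20.7, 243 bp upstream), and eef-1A.2, which encodes translation elongation factor 1A (X chromosome, 7823085 to 7823488, signal 20.2, 367 bp upstream).

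The tagged gene and its partner were not among the thresholded peaks. No pooled candidate lay within 20 kb of eor-1 (chromosome IV, 4793194 to 4799178), and the nearest ones had summits at 4756215 and 4901226. The best candidate near eor-2 (X chromosome, 14603017 to 14608660) ranked 1312 with a signal of 5.17 and lay 254 bp upstream of its start. The better of 2 candidates near unc-119 (chromosome III, 10902641 to 10908935) ranked 2666 with a signal of 3.50. In all, 0 of the 33 thresholded peaks lay within 20 kb of eor-1 or unc-119, which allows a share of up to 9.09% by 3 counts and 10.6% by the exact interval, against 2 of 6660 candidates (Fisher's exact test, two-sided, p = 1).

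The design has a single group, so the comparison it implies is between the replicates. The sites at tos-1, Y39E4B.6, ftt-2 and iff-2 were among the 10 strongest peaks of both replicates, while those at his-37 and gei-4 were among them in 1 replicate only. Of the 33 strongest peaks of replicate 1, 11 had a summit within 200 bp among the 33 strongest of replicate 2 (33.3%, interval 17.96 to 51.83), against 0.0152% expected when summits were shifted along the chromosomes. Of the 1000 strongest of replicate 1, 214 were shared (21.4%, interval 18.9 to 24.1), and from replicate 2 the count was 210 (21%), against 0.402% and 0.420% by shifting. Each excess had a permutation p of 0.001, the smallest that 1000 shifts can give. The shifts place summits anywhere on a chromosome. A preference of both lists for the same kinds of sequence, whatever its cause, would therefore also exceed them, and the excess alone does not show binding by EOR-1. Of the whole lists, 503 of the 2488 peaks of replicate 1 (20.2%) and 498 of the 2610 of replicate 2 (19.1%) had a partner within 200 bp.

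The tos-1 peak ranked 2 in replicate 1 and 1 in replicate 2, and Y39E4B.6 ranked 10 and 2. In contrast, his-37 ranked 95 in replicate 1 and 3 in replicate 2, and gei-4 ranked 3 and 118. Replicate 1 held all 33 thresholded peaks within 200 bp (lower bound 89.4%), and replicate 2 held 29 (87.9%, interval 71.8 to 96.6). The thresholded list was made from the pooled list and both replicate lists, so presence in the replicate lists is partly built in. These counts are a description and not independent evidence of reproducibility. The 4 missing from replicate 2 at that distance were the stronger ftt-2 peak, the let-526 peak, and intronic peaks in abts-4 and pqn-41, which are named here because of that count. In both replicates the median rank of the thresholded peaks was 23, with ranges of 1 to 317 in replicate 1 and 1 to 276 in replicate 2. Only 10 of the 33 were among the 33 strongest of both, and 21 were among the 100 strongest of both. Across 302 of the 500 strongest pooled peaks that had a summit in both lists, Spearman's rho between the signal values was 0.12. These peaks were selected by a signal pooled from both replicates, which narrows the range and can lower the correlation. The value therefore does not measure agreement over the whole lists. Peaks within a library are not independent replicates, so no p-value was attached to this correlation.

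**Figure D1:**
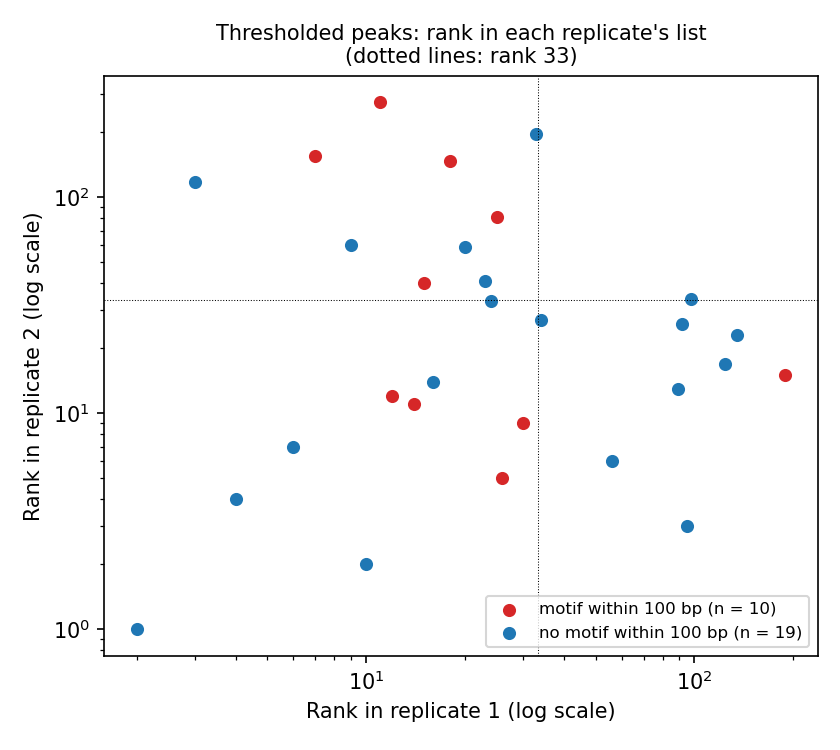
Rank of each thresholded peak in replicate 1 (x axis, log scale) against its rank in replicate 2 (y axis, log scale), for the 29 peaks with a summit within 200 bp in both lists. Red points have a motif match within 100 bp, blue points have none, and dotted lines mark rank 33; 10 points lie at or below rank 33 in both replicates.

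A GAGA-type sequence was found more often at the thresholded peaks than at the other candidates. The 10-base sequence GAGACGCAGA was chosen before the data were examined, as the GAGA-type site of EOR-1. It came from general knowledge and not from a motif database. The data behind that knowledge were not traced, so the choice may not be independent of these data. The sequence occurred with at most 1 mismatch within 100 bp of the summit in 10 of 33 thresholded peaks (30.3%, interval 15.6 to 48.7). Among other candidates it occurred in 725 of 6660 (10.9%). The odds ratio was 3.56 (Fisher's exact test, two-sided, p = 0.0021). The sequence was matched without mismatch in 4 thresholded peaks, including zfp-1 (8802107 to 8802116, minus strand) and the Y111B2A.12 intron (12612664 to 12612673, minus strand). The shorter GAGAGA was present in 19 of 33 peaks (57.6%) against 26.7% of candidates (odds ratio 3.72, Fisher's exact test, p = 2.19e-04). With the 33 strongest peaks of replicate 1 in place of the thresholded set, 27.3% had the 10-base sequence against 14.8%, which did not pass the test (p = 0.0792, exact).

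The strongest promoter peaks mostly lacked the 10-base sequence. None of tos-1, Y39E4B.6, ftt-2, his-37, iff-2, hsp-1, rpl-3 and eef-1A.2 had a match with at most 1 mismatch. The shorter GAGAGA was present at tos-1, hsp-1 and eef-1A.2 but not at the others named. The comparisons that follow count the 10-base sequence only. Of 14 thresholded peaks within 500 bp of a protein-coding start, 1 had a match (at egg-5, named because of this count), against 9 of the 19 others (Fisher's exact test, p = 0.0209, compared after the data were seen). Against promoter candidates, the promoter peaks alone had 7.14% with a match and the candidates 11.9% (p = 1, exact). The 19 other peaks had 47.4% with a match and the other candidates 10.2% (p = 4.66e-05, exact). Outside the thresholded peaks the difference was smaller. In ranks 34 to 100, 10 of 35 promoter peaks (28.6%) and 15 of 32 others (46.9%) had a match (p = 0.138, exact). The shares were 27.9% against 33.7% in the next 400 peaks (p = 0.234, exact) and 17.3% against 23.3% in the next 500 (p = 0.097, exact), and 22.6% against 29.1% over ranks 34 to 1000 together (p = 0.0229, exact). Among candidates ranked above 1000 the order was the opposite, with 9.44% of promoter peaks and 7.70% of others (p = 0.0252, exact).

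Sequence and position changed with rank over the whole pooled list, well below the threshold. The GAGACGCAGA share was 35.0% in the 100 strongest peaks, 30.8% in the next 400, 20.4% in the next 500, 9.50% in the next 4000 and 5.62% in the last 1708. For the 500 strongest it was 31.6% (interval 27.5 to 35.9), against 8.34% (7.63 to 9.09) of the 5708 candidates ranked above 1000, an odds ratio of 5.08 (Fisher's exact test, p = 4.08e-44). Ranked by a single replicate's list the odds ratio was lower, at 3.24 in replicate 1 (26.8% against 10.1%, p = 3.51e-18, exact) and 3.09 in replicate 2 (23% against 8.82%, p = 1.95e-15, exact). The replicate lists are shorter, with 1488 and 1610 candidates above rank 1000. Their odds ratios are therefore not directly comparable with that of the pooled list. In the pooled list GAGAGA followed the same order, with 49.4% against 23.6% (p = 9.25e-33, exact). Of the 461 peaks in ranks 34 to 500 that lay over 1000 bp from a thresholded summit, 147 had the 10-base sequence (31.9%, interval 27.7 to 36.4). At the share of the candidates above rank 1000, 38.4 would have been expected (p = 5.31e-42, exact).

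The strongest peaks lay outside protein-coding genes more often than the weaker candidates and in coding exons less often. Of the 500 strongest, 71.0% were intergenic against 46.9% of those above rank 1000 (Fisher's exact test, p = 1.22e-25), and 2.00% were in coding exons against 17.1% (p = 2.89e-26). Introns held 20.6% against 29.9% (p = 7.53e-06, exact), 5′ UTRs 5.80% against 3.49% (p = 0.0126, exact) and 3′ UTRs 0.400% against 2.58% (p = 6.32e-04, exact). A protein-coding start lay within 500 bp of 50.6% of the 500 strongest and of 36.5% of those above rank 1000 (p = 1.08e-09, exact). A summit in both replicate lists was found for 85.0% of the 100 strongest, 54.3% of the next 400 and 0.293% of the last 1708, and for 60.4% of the 500 strongest against 1.66% above rank 1000. The pooled list was called on the reads of the same replicates and the replicate lists are shorter, so a fall with rank is built in and no test is given.

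**Figure D2:**
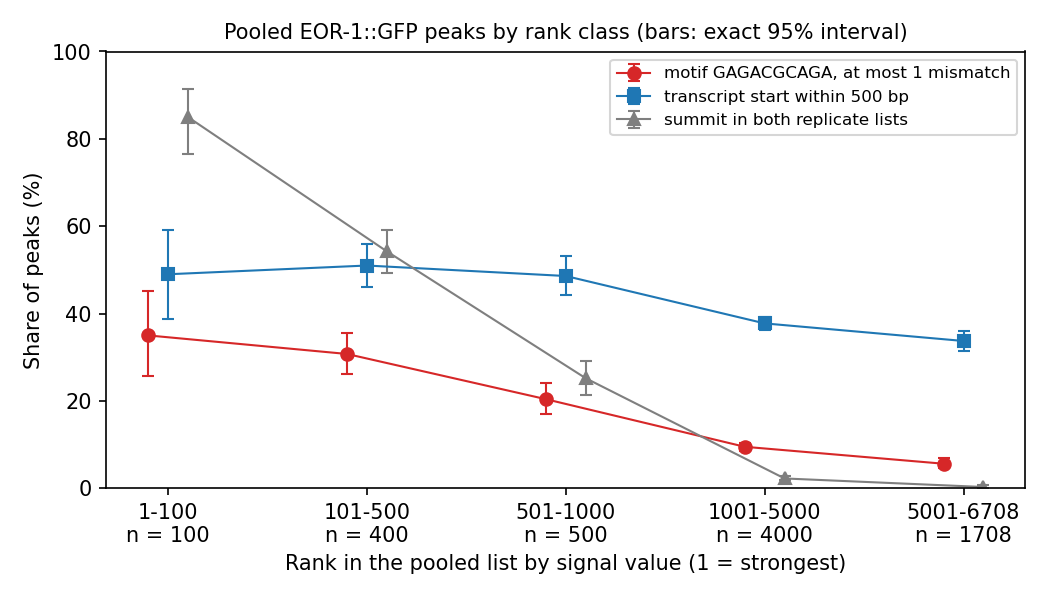
Share of pooled peaks in percent (y axis) by rank class of the authors' signal value (x axis, number of peaks under each class), with exact 95% binomial intervals as bars. Points show the share with the GAGACGCAGA sequence at no more than 1 mismatch, the share within 500 bp of a protein-coding start and the share with a summit in both replicate lists; the sequence share goes from 35.0% in the 100 strongest to 5.62% in the last 1708.

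Parts of the same sequence came out first when all 8-mers were compared. The peaks, candidates and window were those of the test above, so this is not separate evidence that the sequence was more frequent. It shows that no other 8-mer had a lower p-value. Of 32894 8-mers compared within 100 bp of summits, the 3 with the lowest p-values in the 500 strongest peaks against candidates above rank 1000 were AGACGCAG, GAGACGCA and GACGCAGA, all contained in GAGACGCAGA. AGACGCAG was present in 20.4% against 5.43% (Fisher's exact test, Benjamini-Hochberg p = 1.16e-22). In total 309 8-mers were more frequent and 31 less frequent in the strongest peaks at an adjusted p below 0.05. Matches to the 10-base sequence were 8.43 times as dense within 100 bp of the summit as 200 to 400 bp away in the 500 strongest peaks (interval 6.10 to 11.8), and 2.78 times as dense (2.44 to 3.17) above rank 1000.

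**Figure D3:**
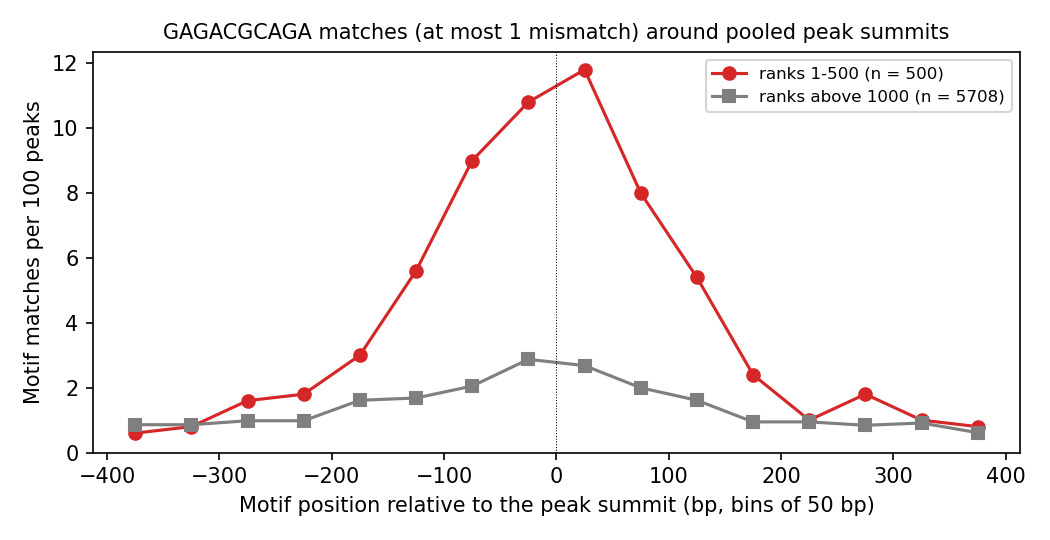
Matches to GAGACGCAGA with no more than 1 mismatch per 100 peaks (y axis), in bins of 50 bp by distance from the summit in bp (x axis), for the 500 strongest pooled peaks (red) and the 5708 ranked above 1000 (grey). Matches within 100 bp of the summit were 8.43 times as dense as at 200 to 400 bp in the 500 strongest.

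Thresholded peaks did not differ detectably from the other candidates in promoter share or in the share on the X chromosome. Of the 33, 14 lay within 500 bp of a protein-coding start (42.4%, interval 25.5 to 60.8), against 38.5% of candidates (Fisher's exact test, p = 0.72). Summits shifted along the chromosomes gave 22.4% (permutation p = 0.014). On the X chromosome there were 8 of 33 (24.2%, interval 11.1 to 42.3) against 20.6% (p = 0.665, exact). Chromosome III held 10 of 33 (30.3%) against 15.6% of candidates, an odds ratio of 2.35 that did not pass adjustment over the 6 chromosomes (Fisher's exact test, p = 0.0291, Benjamini-Hochberg p = 0.174, added after the data were seen). Chromosome I held 5, II and V 4 each, and IV 2. Within 200 bp of a tRNA, rRNA, snRNA or snoRNA gene there was 1 of 33 (3.03%) against 3.23% of candidates (p = 1, exact), and that peak was at sls-2.4, a spliced leader RNA gene beside egg-5. With 33 peaks the intervals are wide, and the 1000 strongest pooled peaks had a higher promoter share than the remaining candidates (49.6% against 36.01%, p = 9.26e-16, exact) and a higher share near these RNA genes (4.70% against 2.94%, p = 0.00598, exact).

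Ribosomal protein genes were the gene group found more often than expected among the 1000 strongest pooled peaks. Of 33 ribosomal protein genes with any pooled candidate, 17 had one of the 1000 strongest, an odds ratio of 4.42 (Fisher's exact test, p = 4.10e-05, Benjamini-Hochberg p = 9.42e-04 adjusted over 23 gene lists fixed before the data were examined). The strongest of them were at rpl-3 (rank 27, signal 20.7), rps-1 (rank 43, signal 18.5), rpl-32 (rank 109, signal 14.01) and rpl-15 (rank 164, signal 12.2), of which rps-1, rpl-32 and rpl-15 were named after their values were seen. The background was the 2980 genes with any pooled candidate, of which 588 had one of the 1000 strongest. In the 1000 strongest peaks of a single replicate, against the genes of that replicate's list, the call was lost: the odds ratio was 2.07 in replicate 2 (adjusted p = 0.97, exact) and 1.55 in replicate 1 (adjusted p = 0.726, exact). Peaks at paralogous genes such as those of histones and ribosomal proteins depend on how reads were placed, which is not given in the sources used here.

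No other list passed the adjusted threshold in the 1000 strongest peaks. Mediator genes had 4 of 6 (dpy-22, mdt-26, mdt-27 and sur-2, adjusted p = 0.141, exact) and insulin, stress and longevity genes 5 of 9 (akt-2, aak-2, hlh-30, pqm-1 and smk-1, adjusted p = 0.141, exact). SWI/SNF genes had 3 of 5 (let-526, pbrm-1 and swsn-7, adjusted p = 0.32, exact), and these member names are given because of their small counts. Chaperones had 6 of 16, translation factors 6 of 15 and collagens 0 of 14 (each adjusted p = 0.349, exact). Actin cytoskeleton genes had 6 of 17 (adjusted p = 0.354, exact) and heterochronic genes 3 of 7 (adjusted p = 0.366, exact). Germline genes had 1 of 1 (adjusted p = 0.454, exact), body wall muscle genes 4 of 11 and excretory system genes 2 of 5 (each adjusted p = 0.493, exact). The lists of Ras, MAPK and vulval genes (1 of 6), Wnt (1 of 5), Hox (0 of 1), histones (1 of 5), molting (1 of 5), vacuolar ATPase (2 of 7), epidermis and junctions (1 of 9), neurons and synapses (1 of 8), intestine (1 of 6), cell death (0 of 3) and cell cycle (1 of 8) each had an adjusted p of 1 (exact).

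At the thresholded peaks alone, 19 genes were assigned and 0 of the 23 lists passed the adjusted threshold by Fisher's exact test. An unadjusted p below 0.05 was reached by 3 lists. These were translation factors with 2 of 15 genes (iff-2 and eef-1A.2, odds ratio 26.7, p = 0.00385, adjusted p = 0.0885, exact), histones with 1 of 5 (his-37) and SWI/SNF with 1 of 5 (let-526), the last pair each with p = 0.0315 and an adjusted p of 0.241 (exact). Chaperones had 1 of 16 (hsp-1, adjusted p = 0.561, exact) and ribosomal proteins 1 of 33 (rpl-3, adjusted p = 0.88, exact). The other 18 lists, among them the Ras, Wnt and Hox lists, had 0 genes at a thresholded peak.

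The authors gave each list on ce10 as well as ce11, and the numbers of peaks differed between builds. On ce10 the replicates had 2652 and 2637 peaks, the pooled list 6512 and the thresholded list 25, so the thresholded list was 1.32 times as long on ce11. The thresholded peaks were the 33 highest ranked of the pooled list on ce11 and the 25 highest ranked on ce10. On ce11 the weakest of them had a signal of 19.3 and the next pooled candidate 19.1. Chromosome III held 10 thresholded peaks on ce11 and 7 on ce10, and the X chromosome 8 and 6. Coordinates were not converted between builds, so no ce10 peak was matched to a ce11 peak.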

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

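Alternatives were run 83 times over 14 results. The outcome was fixed in 15, by removing no peak, by counts too few to pass or by an order built into the lists, and 46 of the other 68 kept the direction and the side of the threshold or stayed within the interval. The tests of the 500 strongest peaks in the gene lists, the GC-matched background, merged summits, and every alternative for the lists at the 1000 strongest peaks were chosen after the data were seen. Sharing between replicates, found at 14.5% to 25.9% of the 1000 strongest peaks over its alternatives, and the shares of promoters and of GAGACGCAGA among the 500 strongest kept direction and call, although the GAGACGCAGA share went from 31.6% to 23% without replicate 1 and 26.8% without replicate 2. The promoter share of thresholded peaks was 49.6% and passed the test with the 1000 strongest peaks, and was below the candidates' share at 21.2% with starts within 250 bp. With a single replicate's 33 strongest peaks it was 36.4% without replicate 2, below the candidates, and 48.5% without replicate 1. The GAGACGCAGA share was 27.3% without replicate 2, no longer past the threshold, and 33.3% without replicate 1, and for promoter peaks alone it was 7.14%, below promoter candidates. The X chromosome share was below that of candidates at 12.5% in the stronger 16 thresholded peaks and at 21.2% without either replicate. The share near noncoding RNA genes turned higher than that of candidates at 4.70% in the 1000 strongest peaks. The number of gene lists past the threshold went from 0 at the thresholded peaks to 1 with the 1000 strongest peaks, 1 with the 500 strongest and 1 against all protein-coding genes. For the 1000 strongest peaks it was 1, and went to 10 against all protein-coding genes, a background that also holds genes with no candidate, to 3 with starts within 2000 bp, and to 0 without either replicate. The odds ratio of ribosomal protein genes was then between 1.55 and 2.50 without 1 of the replicates, and past the threshold in none of these settings at 1000 bp. With starts within 2000 bp it passed in replicate 2 against the genes of all 3 lists (2.60, adjusted p = 0.039, exact). It did not pass there against that replicate's own list (2.46, adjusted p = 0.56, exact). In replicate 1 it passed neither against its own list (1.63, adjusted p = 0.715, exact) nor against all 3 lists (1.61, adjusted p = 0.413, exact). The causes were not tested. Comparing the 5000 strongest peaks of the replicates was not run, since each replicate list is shorter than that. Leaving out peaks near rRNA genes removed 0 peaks and so tested nothing. With 33 thresholded peaks, shares have intervals wide enough to hide moderate differences, and depth is unknown. No paired analysis was possible because the study has 1 group.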

Other observations

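The tests of 8-mers in peaks lacking the sequence, of repeated matches, of RNA gene types and of wider gene assignment were chosen after the main results were seen. So were the density around the summit, the comparison at ribosomal protein, translation factor and chaperone genes, and the comparisons of promoter peaks below. Of the 500 strongest pooled peaks, 206 (41.2%) had neither GAGACGCAGA nor GAGAGA within 100 bp, against 72.6% of those above rank 1000. Within these peaks, 23 of 32821 8-mers were more frequent in the strongest at a Benjamini-Hochberg p below 0.05, led by AAACACGC, in 7.28% against 0.748% (Fisher's exact test, adjusted p = 3.74e-05), then the overlapping CAAACACG, in 5.83% against 0.579% (adjusted p = 6.98e-04, exact), and CGCTCCAC, in 5.83% against 0.676% (adjusted p = 0.00176, exact). Peaks with the 10-base sequence held more than 1 match in 30 of 158 cases among the 500 strongest (18.99%) and in 52 of 476 above rank 1000 (10.9%, Fisher's exact test, p = 0.0132). Peaks with a summit in 1 replicate list and in both had the sequence in 26.7% and 36.5% of cases among the 100 strongest, 28.2% and 33.2% in the next 400, 21.3% and 19.8% in the next 500, 15.2% and 15.7% in the next 1000, and 8.59% and 0 of 25 above rank 2000, with no test between them.

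With genes assigned within 2000 bp of a summit, heterochronic genes, which time larval development, had 8 of 11 members at the 1000 strongest peaks (odds ratio 11.6, Fisher's exact test, Benjamini-Hochberg p = 0.00167), against 3 of 7 within 1000 bp. Insulin, stress and longevity genes had 7 of 12 (odds ratio 6.09, adjusted p = 0.0203, exact). Against a single replicate's own list neither passed: the heterochronic odds ratio was 4.58 in replicate 1 (adjusted p = 0.715, exact) and 4.91 in replicate 2 (adjusted p = 0.56, exact), and that of the insulin list 1.299 (adjusted p = 1, exact) and 3.27 (adjusted p = 0.603, exact). Against the genes of all 3 lists, heterochronic genes passed in replicate 1 (adjusted p = 0.0125, exact) and replicate 2 (adjusted p = 0.0124, exact), and insulin genes in replicate 2 (adjusted p = 0.0128, exact) but not in replicate 1 (odds ratio 2.57, adjusted p = 0.339, exact). Within 1000 bp, where neither list passed, examples named after their values were seen were lin-28 (rank 213, signal 11.3) and alg-1 (rank 804, signal 6.54, with an exact GAGACGCAGA). Others were akt-2 (rank 231, signal 11.01, with 1 mismatch) and aak-2 (rank 262, signal 10.5, with an exact match). The remaining members within 1000 bp were lin-66, hlh-30, pqm-1 and smk-1. Like lin-28, they had no match with at most 1 mismatch. Of the RNA gene types within 200 bp of the 1000 strongest peaks, tRNA genes had 3% against 1.85% of other candidates (Fisher's exact test, p = 0.0269, Benjamini-Hochberg p = 0.108). The snoRNA genes had 1.40% against 0.960% (adjusted p = 0.46, exact) and snRNA genes 0.300% against 0.148% (adjusted p = 0.525, exact).

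The share of GAGACGCAGA was higher in the strongest pooled peaks, and 3 technical explanations were tested. The strongest peaks had more GC, with a median of 45.8% against 39.8%, but weaker candidates weighted to the same GC had the sequence in 13.3%, below the lower bound of 27.5% for the 500 strongest. The weighting was by GC only. It did not allow for gene parts, although coding exons held 17.1% of the weaker candidates and 2.00% of the 500 strongest. Base composition was tested with 100 permuted versions, of which 0 reached the sequence's ratio of shares of 3.79; the highest, AGAGAGGCAC, came near it at 3.56, and the median was 1.35. Sequence of the wider region would give no higher density at the summit, but matches there were 8.43 times as dense as 200 to 400 bp away (interval 6.10 to 11.8). Above rank 1000 the density at the summit was also higher, by 2.78 times (2.44 to 3.17). A smaller excess at summits was thus present in the weaker candidates too. That EOR-1 itself recognises the sequence at these sites, many of them below the IDR threshold, is a hypothesis that may account for the pattern, and no biological explanation was tested because the design has 1 group.

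Strong promoter peaks often lacked the sequence, for which a candidate explanation is signal at highly transcribed promoters that does not depend on it. Genes of ribosomal proteins, translation factors and chaperones stood in for highly transcribed genes. They were chosen after the main results were seen, and the transcription of each gene was not measured. The comparison therefore covers these gene groups and not highly transcribed genes as such. Of promoter peaks at ribosomal protein, translation factor and chaperone genes in the 1000 strongest, 1 of 28 had the sequence (3.57%, interval 0.0904 to 18.3), at rpl-41.2, against 109 of 468 other promoter peaks (23.3%, Fisher's exact test, p = 0.00976), and 1 of 24 against 108 of 458 in ranks 34 to 1000 (p = 0.0235, exact). Without those genes the odds ratio of the sequence at promoters against other peaks went from 0.673 (interval 0.500 to 0.903) to 0.717 (0.532 to 0.964, p = 0.0244, exact) in ranks 1 to 1000. In ranks 1 to 100 it went from 0.329 to 0.391 (interval 0.144 to 1.01, p = 0.0353, exact). Both ranges include the thresholded peaks in which the pattern was first seen, so they cannot decide whether those genes are the whole cause. The call ended in the 33 thresholded peaks (0.0916, interval 0.00181 to 0.851, to 0.132, interval 0.00254 to 1.296, p = 0.0976, exact), in ranks 1 to 500 (0.642, interval 0.430 to 0.954, to 0.692, interval 0.462 to 1.03, p = 0.0651, exact) and in ranks 34 to 1000, which leave out the peaks that prompted the question (0.713, interval 0.528 to 0.962, to 0.753, interval 0.556 to 1.02, p = 0.0646, exact), with fewer promoter peaks and odds ratios nearer 1. Whether the larger difference among the strongest peaks arose by chance cannot be told, because ranks 34 to 100 gave p = 0.138 (exact). Over ranks 34 to 1000 a smaller difference remained (22.6% against 29.1%, Fisher's exact test, p = 0.0229). This argues against chance in the thresholded peaks as its only source, although the range was chosen after the data were seen. Transcription was not measured here. Highly transcribed genes outside these groups, binding through another protein and signal of open chromatin therefore stay open, and no biological explanation was tested.

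No pooled candidate lay near eor-1, the gene carried by the transgene. The gap around it, from 4756215 to 4901226 on chromosome IV, was 145011 bp long, a length reached by 18 of 6702 gaps between neighbouring candidates. Of 19973 protein-coding genes, 994 (4.98%, interval 4.68 to 5.29) had no candidate within the 36979 bp that separated eor-1 from the nearer candidate. This share lies next to the 5% set in advance. Neighbouring genes share gaps, so the interval, which treats genes as independent, cannot settle on which side it falls. The test also used the shorter side of the gap only, so chance cannot be told apart. Extra transgene copies that raise the control signal may remove candidates at the gene, but the gap extended 102047 bp on its longer side; the bound set in advance, 40 kb, was wrong as a test, because a gap beyond the transgene does not show what happened inside it. Coverage of the control was not analysed here, and no biological explanation was tested.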
